A study of Mus musculus with 4 samples.

How the data were processed

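Lungs of WT and Vegfr2Y949F mice on the C57BL/6J background were studied after 6 weeks of hypoxia, per the labels. The 4 single-cell RNA libraries were 2 of WT and 2 of Vegfr2Y949F lungs, and each genotype had a library of a set A and one of a set B. Each suspension pooled lung cells of 2 mice, per the series' design text, so the 4 libraries hold cells of 8 mice. The lungs were minced and digested with collagenase and DNase, the suspension was passed through strainers, red blood cells were lysed, and single cells were captured in 10x Genomics droplets and sequenced on a NovaSeq, per the labels' protocols. The labels do not say what the set letter marks, and do not give the sex of the mice in a pool.

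The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and droplet barcode, not normalized. Cell Ranger 6.1.1 wrote them, per the file headers. The genome build was mm10, and fastp, UMI-tools and Seurat 4.1.0 were also used, per the submitters' processing notes. The deposited barcodes had 500 UMIs or more and included barcodes with up to 94.3% mitochondrial UMIs. The aligner's settings and the gene annotation were not given in the sources used here. Of the 31253 gene identifiers in the files, 31107 were found in the GENCODE M21 annotation of the same build, 30203 of them under the same symbol, and the coordinates printed here come from that annotation. For 43 symbols shared by more than 1 identifier, the identifier was kept in the name. The authors' cell type annotation was not used here, so clusters and names were rebuilt and can differ from the study's.

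A barcode was kept as a cell with at least 500 detected genes, at least 1000 UMIs and under 15% of UMIs from mitochondrial genes. Doublets were scored with Scrublet (in scanpy 1.11.5) within each library. Its automatic threshold marked 0, 387, 64 and 0 cells of the WT A, Vegfr2Y949F A, WT B and Vegfr2Y949F B libraries, so the highest 8% of scores per library, the assumed doublet rate, were removed instead. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen over the libraries, leaving out sex-linked, mitochondrial, haemoglobin and ribosomal protein genes and Kdr. Cells were clustered on 40 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2, resolution 1, seed 0) and no integration of libraries. A cluster took a type's name where at least 3 of that type's markers were detected in at least 20% of its cells and the type's score led the next by at least 0.3. Clusters with over 30% doublets, with fewer than 10 cells, with markers of another lineage, with more markers of another class than of their own among the 10 leading genes, or with a median UMI count under 0.333 of their own libraries' and no own marker among these genes stayed unnamed. The markers were fixed before the data were examined, and the thresholds for naming afterwards.

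UMI counts were summed per library and cell type, and the 2 WT sums were compared with the 2 Vegfr2Y949F sums, since cells are not replicates. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, the filterByExpr filter and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. All endothelial cells were the general capillary, aerocyte, arterial and venous types together. Each other named type was tested where every library held at least 20 of its cells. Numbers of cells per type were compared with the same test, with the cells kept per library as library size. The 29 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 where at least 4 members passed the filter, and again with an estimated correlation. Markers of the cell types were tested in the endothelial sums in the same way. After the results were seen, they were also tested in each of 17 types, as a family of 134 tests. To estimate endothelial RNA in another type, the CPM of 5 endothelial markers (Pecam1, Cdh5, Cldn5, Tie1 and Egfl7) was divided by their CPM in endothelial cells of the same library, and that share of the endothelial profile was subtracted. Some of these genes can be expressed by other cells, such as Pecam1 in leukocytes. Whether a change differed between 2 cell types was tested with the same tool, in a model with terms for library, cell type and the interaction of type and genotype. Levels are CPM, the summed counts scaled to a common library total. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333, so edgeR's adjusted p is the test reported. The p-values of edgeR measure the spread between 2 pools per genotype. Those of camera compare the members of a list with the other genes at the preset correlation. A small camera p therefore does not show how well a change repeats between pools.

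The genes named were chosen by a rule fixed before the data were examined. In all endothelial cells it takes the 12 largest rises and the 12 largest falls among genes past the threshold with an average log2 CPM of at least 4 and both mutant libraries beyond both WT libraries, gene models left out. In every other type it takes 5 and 5. It adds up to 4 members with the smallest adjusted p of each list reported, the genes Kdr, Flt1, Nrp1 and Vegfa, and genes called in the same direction in at least 3 types. Genes outside the rule are marked in the text as chosen after their values were seen.

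The edgeR and camera steps were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. A common dispersion was used for all genes of a sum, and each gene was drawn independently, without an effect of the set letter. For all endothelial cells (13910 genes), 49.5% of genes changed by a log2 fold of 1 and 98.0% of those changed by 2 were called, with 10 false among 155 calls. For general capillary cells (13126 genes) the shares were 51.0% and 99.0%, with 7 false of 152, and for aerocytes (11482 genes) 71.7% and 100%, with 7 false of 177. Of 100 lists without a shift, 6, 2 and 2 had a p under 0.05. Since the simulated genes were independent, these counts do not test the preset correlation on genes that are correlated. The shares of changed genes called may also be lower in the real data. In a simulated composition of 24 types, at a dispersion of 0.05, a type changed by 4 times had an adjusted p of 1.86e-05 and 0 other types were called. That dispersion was set and not estimated from the data. In the data the SE of the log2 fold change of a type's share was 0.42 (arterial endothelial cells) to 1.35 (nonclassical monocytes). The simulation therefore does not show which changes in the real cell numbers could be called.

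The alternatives tried were DESeq2 1.42.0, RLE factors, no low-count filter, each library left out in turn, the set letter as a block, doublets kept, stricter cells (at least 1000 genes and under 5% mitochondrial UMIs), Leiden resolution 2, genes of the X and Y chromosomes removed, equal weight of the endothelial types, TMM factors on cell numbers, and shares within a lineage. An analysis without mixed cells and one without cluster 8 were added after seeing the data, and the second removed 589 and 775 cells of mutant A and B and 52 and 68 of WT A and B. Mixed cells had at least 1% of UMIs from haemoglobin genes or, outside neutrophils and monocytes, from S100a8 and S100a9. Intervals of a library's share are 95% Wilson intervals and cover counting error only. Unnamed clusters and barcodes that failed the filters entered no test between genotypes. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. For Gm8797, 1 further test that needs another gene is not reported here.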

Results

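Single-cell RNA profiles were collected from lungs of WT mice and of Vegfr2Y949F mice that had spent 6 weeks in hypoxia, an exposure that raises pulmonary artery pressure and remodels lung vessels in mice. The genotype's name gives a tyrosine-to-phenylalanine change in VEGFR2, the main signalling receptor for VEGF-A on endothelial cells, which the gene Kdr encodes. The tyrosine is known as a docking site for the adaptor TSAd (gene Sh2d2a) in VEGF-driven vascular permeability. The question was how cell clusters and gene expression of hypoxic lungs differ between the genotypes. Each genotype had 2 libraries, A and B, and each library pooled the lungs of 2 mice. The mice were 6 to 8 weeks old, and no library of normoxic lungs was analysed here. All levels below are mean ± SD of 2 libraries per genotype unless a library is named.

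The WT libraries held 13567 (A) and 12568 (B) barcodes with 83606389 and 95677964 UMIs. The Vegfr2Y949F libraries, called mutant below, held 15160 (A) and 11992 (B) barcodes with 96521589 and 84859281 UMIs. After filters and doublet removal, 10783 and 9715 WT cells and 11446 and 9304 mutant cells were kept. Their median UMI counts were 4339, 5472, 4312 and 5548.5 in the same order, so the B libraries were deeper per cell than the A libraries in both genotypes. Counts of general capillary cells differed between every pair of libraries by more than sampling noise (chi-square per degree of freedom 14.3 to 102 over genes), so the 4 libraries were treated as 4 samples. The value was 42.8 and 14.3 for the pairs of set A and set B, and 54.6 and 74.3 for the pairs of WT and of mutant libraries. It was 41.4 for mutant B with WT A and 102 for mutant A with WT B.

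Clustering gave 24 named cell types. General capillary cells, the capillary type that can act as a progenitor, were the most numerous with 16624 cells, followed by alveolar fibroblasts (3391), neutrophils (3339) and aerocytes (3216), the large capillary cells specialised for gas exchange. Arterial (790), venous (1707) and lymphatic (317) endothelial cells, alveolar type 1 cells (1093) and T cells (1457) were also separated. The 4701 cells in unnamed clusters made up 11.4 ± 1.32% of WT and 11.5 ± 1.34% of mutant cells. General capillary cluster 5 (1934 cells) was led by interferon-induced genes such as Ifit1 and Ifit3. General capillary cluster 8 (1484 cells) was led by Plvap, Esm1 and Adgrl3, with the interferon-induced Ifit1 and Ifit3 also among its 10 leading genes. When general capillary cells were clustered again without 214 genes at an unadjusted p under 0.05 between genotypes, 50.8% of the mutant cells of cluster 8 lay in a cluster that was 99.2% mutant, with 714 of its 779 cells from mutant B. A further 34.6% lay in one that was 98.0% mutant, with 505 of its 547 cells from mutant A. These clusters split the mutant libraries as well as the genotypes. Other clusters split the WT libraries, such as one with 829 cells of WT A and 129 of WT B and one with 189 of WT A and 863 of WT B. Libraries were not integrated, so separation by genotype and by library cannot be told apart here. Neutrophil cluster 2 came mostly from mutant library A (1870 of 3339 cells), and the lymphatic cluster (162 of 317) and the alveolar type 2 cluster (89 of 158) came mostly from WT library B.

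Kdr itself was read at a similar level in both genotypes. In all endothelial cells Kdr (ENSMUSG00000062960, mm10 chromosome 5, 75932827 to 75978458, minus strand) stood at 420 ± 58.2 CPM in WT (461 in A and 378 in B) and 447 ± 5.86 CPM in mutants (451 and 443), a log2 fold change of 0.09 (SE 0.18, edgeR adjusted p = 1.00). Aerocytes carried the highest Kdr level among the capillary types, 1230 ± 197 CPM in WT and 1215 ± 122 CPM in mutants. General capillary cells had 196 ± 21.4 and 200 ± 3.43 CPM, and without cluster 8, a setting chosen after seeing the data that removes almost only mutant cells (589 and 775 against 52 and 68 of WT), the log2 fold change of Kdr in general capillary endothelial cells was -0.22 (adjusted p = 1.00). The related receptor Flt1 (VEGFR1, ENSMUSG00000029648, chromosome 5, 147561604 to 147726011, minus strand) had 860 ± 99.9 CPM in WT and 887 ± 101 CPM in mutants, and the co-receptor Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363, plus strand) had 597 ± 80.2 and 608 ± 18.9 CPM. The ligand Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, minus strand) had 389 ± 15.3 and 404 ± 33.6 CPM in endothelial cells, and in alveolar type 1 cells, the highest of the types tested, 3769 ± 110 and 3747 ± 85.5 CPM. None of these differences exceeded the spread between libraries (adjusted p = 1.00 for each in all endothelial cells). Counts per gene do not show the changed codon, so Kdr does not check the genotype labels, and without WT library B its log2 fold change was -0.046 (adjusted p = 1.00).

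The mix of cell types was the first comparison. Classical monocytes, blood-derived precursors of lung macrophages, made up 0.547 ± 0.537% of WT cells (0.167% in A and 0.926% in B) and 1.40 ± 0.0755% of mutant cells (1.45% and 1.34%), a log2 fold change of 1.35 (SE 0.93, edgeR adjusted p = 0.977). Neutrophils made up 5.33 ± 0.352% and 10.2 ± 8.72%, and the higher mutant mean came from library A (16.3%, 95% Wilson interval 15.7 to 17.0) and not from library B (4.01%, 3.63 to 4.43). General capillary cells made up 43.2 ± 10.7% of WT cells, with 50.8% in A and 35.7% in B, and 36.9 ± 1.39% of mutant cells. Aerocytes were 7.71 ± 1.25% and 7.78 ± 0.861%, venous cells 4.56 ± 0.119% and 3.76 ± 0.638%, and arterial cells 1.71 ± 0.168% and 2.11 ± 0.142%. Smooth muscle cells, which thicken arterial walls in hypoxic lungs, were 0.675 ± 0.0497% of WT and 0.535 ± 0.0719% of mutant cells.

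Of the 24 types, 0 passed edgeR's test on cell numbers, and 0 had an unadjusted p under 0.05 (each adjusted p = 0.977). All endothelial cells together were 57.2 ± 11.9% of WT cells (65.6% in A and 48.8% in B) and 50.6 ± 1.76% of mutant cells (exact permutation p = 1, two-sided, where 0.333 is the smallest p that 2 against 2 libraries can give). T cells were 0.705% of WT library A and 6.82% of WT library B, against 2.20% and 5.01% in the mutants. Without WT library B, 5 types were called higher in the mutants, classical monocytes (log2 fold change 3.06) and T cells (2.35, from -0.06) among them.

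**Figure D1:**
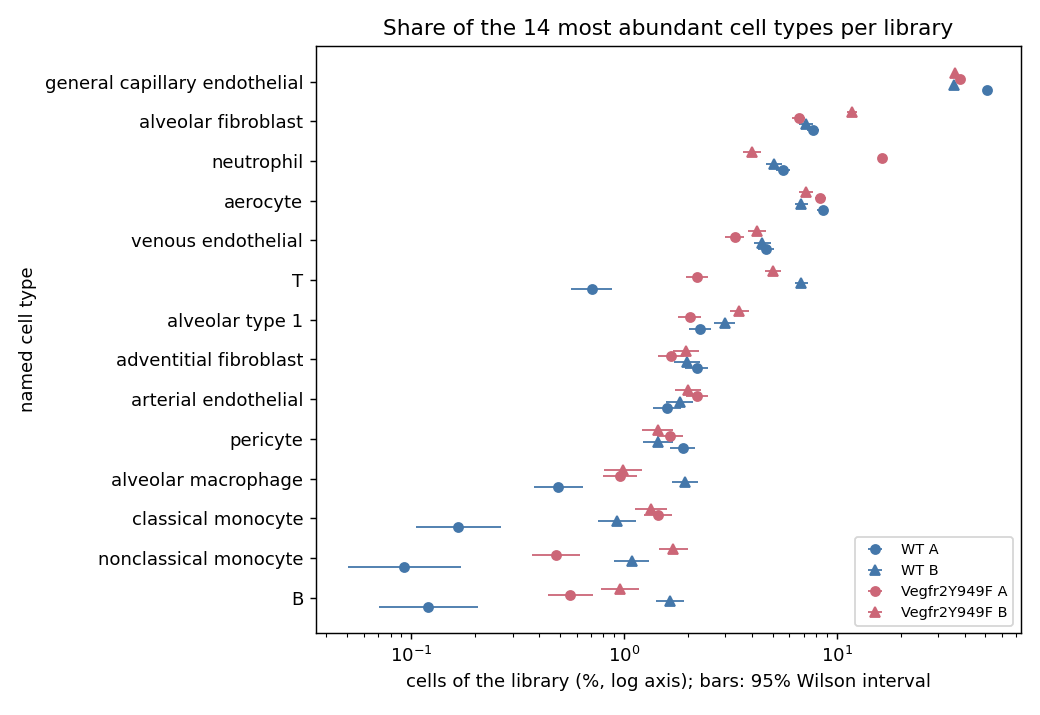
Share of the 14 most abundant named cell types in each library, as percent of the cells kept, on a log axis. Points are single libraries (blue WT, red Vegfr2Y949F, circles A, triangles B) and bars are 95% Wilson intervals of counting error only; T cells range from 0.705% to 6.82% between the WT libraries, wider than the gap between genotypes.

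Gene by gene, edgeR without a block for the set letter separated the genotypes in none of 3 endothelial sums, those of all endothelial, general capillary and aerocyte cells. With the set letter as a block it called 13, 0 and 43 genes in these sums in that order, and the labels do not say what the letter marks. Among the other endothelial types, edgeR without the block called 3 haemoglobin genes in arterial cells. Among all endothelial cells (22337 cells, 36410473 to 43561645 UMIs per library, 13910 genes), edgeR called 0 genes, with 171 at an unadjusted p under 0.05 (1.23%) and a smallest adjusted p of 0.960, and DESeq2 called 9, all higher. In general capillary cells (13126 genes) edgeR called 0, with 214 at an unadjusted p under 0.05 (smallest adjusted p 0.754, Samd5), and DESeq2 called 14, all higher. In aerocytes (11482 genes) edgeR called 0, with 188 at an unadjusted p under 0.05 (smallest adjusted p 0.983, Gm8797), and DESeq2 called 3, all higher. The rule for named genes therefore selected no gene by fold change in these 3 sums. Mutant libraries lay beyond both WT libraries for 1539 genes above and 1559 below in all endothelial cells, 22.3% of those tested. Chance gives 33.3% if the libraries are exchangeable, which does not allow for libraries of a set that move together.

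The 3 aerocyte genes called by DESeq2, named here after their values were seen, were Gm8797 (log2 fold change 1.12, adjusted p = 0.00636), Plvap (1.04, 0.0190), which forms the diaphragms of endothelial fenestrae and caveolae, and the beta-globin gene Hbb-bt (1.26, 0.0462). In each library 1% of the aerocytes held 94.4% to 97.7% of the haemoglobin UMIs, with 13 and 7 haemoglobin-rich aerocytes in mutant A and B and 4 and 3 in WT A and B, and erythroid markers were higher in aerocytes (median 1.05, adjusted p = 1.33e-17, and 0.817 with an estimated correlation). Camera also called the general capillary markers, which include Plvap, higher in aerocytes (4 of 6 members, median 0.23, adjusted p = 0.00359). The venous markers were called higher there too (0.23, 0.0479), each of these 2 at 0.817 with an estimated correlation. Gm8797 is a single-exon gene model on chromosome 3 that resembles the polyubiquitin gene Ubb, and also had the value 1.22 in all endothelial cells (34.0 ± 5.42 CPM in WT and 79.2 ± 10.8 CPM in mutants). Without the low-count filter edgeR called 44, 64 and 29 genes in all endothelial, general capillary and aerocyte cells. Leaving out a library changed the counts too: without WT A to 9, 20 and 9, without WT B to 28, 11 and 19, without mutant A to 1, 3 and 0, and without mutant B to 1, 1 and 7.

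The 29 gene lists asked whether sets of related genes moved together in all endothelial cells. Camera called 13 lists, 10 higher and 3 lower in the mutants, and 14 had an unadjusted p under 0.05. With an estimated correlation between genes 0 lists were called, and the adjusted p of these 13 was then 0.347 to 0.528. No member of any list was called over all genes tested.

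Heat shock genes, which encode chaperones, fell. All 11 members were lower in the mutants, 9 of them in both mutant libraries below both WT libraries, with a median log2 fold change of -0.47 (camera adjusted p = 2.19e-14, and 0.347 with an estimated correlation). The median was larger within set A (-0.79) than within set B (-0.27). Hsph1 had -0.81 (SE 0.25), Hspe1 -0.68 (SE 0.24), Hspb1 -0.92 (SE 0.35) and Hsp90aa1 -0.47 (SE 0.22). Hypoxia response genes fell with 16 of 19 members lower and a median of -0.25 (adjusted p = 0.000244, and 0.439 with an estimated correlation). Among them were the glycolytic genes Tpi1 (-0.35, SE 0.15) and Aldoa (-0.33, SE 0.21), the collagen hydroxylase P4ha1 (-0.64, SE 0.37) and Ddit4 (-0.26, SE 0.16). MHC class II genes, which present antigen and are expressed by lung capillaries, fell with 7 of 9 members lower and a median of -0.36 (adjusted p = 1.22e-05, and 0.347 with an estimated correlation). H2-DMb1 had -0.40 (SE 0.17), H2-Eb1 -0.45 (SE 0.19), H2-Ab1 -0.39 (SE 0.18) and H2-DMa -0.36 (SE 0.18). Adjusted over the list alone, 0 members of the 3 lists were called. Without mutant A the hypoxia call ended (adjusted p = 0.0929), and the MHC class II call ended without WT A (0.0503) and without mutant B (0.233).

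Interferon response genes rose, with 16 of 21 members higher and a median of 0.25 (adjusted p = 8.56e-09, and 0.347 with an estimated correlation). Their leading members were the interferon-induced Ifi44 (0.63, SE 0.13), the antiviral Rsad2 (0.73, SE 0.18), Ifit2 (0.51, SE 0.16) and the nucleic acid sensor Zbp1 (0.43, SE 0.15). Angiogenesis and tip cell genes rose as a list, with 13 of 16 members higher, a median of 0.11 and a mean of 0.36 (adjusted p = 1.56e-05, and 0.347 with an estimated correlation). That list was carried by Esm1 (2.53, SE 0.60), a VEGF-induced secreted tip cell protein, the chemokine receptor Cxcr4 (1.40, SE 0.31) and the Tie2 ligand Angpt2 (1.03, SE 0.25), the 3 members called when adjusted over the list alone. Esm1 also led general capillary cluster 8, and without that cluster, a setting chosen after seeing the data, Esm1 in all endothelial cells had 1.34, Cxcr4 in all endothelial cells 0.76 and Angpt2 in all endothelial cells 0.51, with the angiogenesis list (adjusted p = 0.00168) and the interferon list (0.00703) still called. Without mutant B, Esm1 in all endothelial cells had 1.27 (adjusted p = 0.485). Adjusted over the list alone, 0 interferon genes were called, and the interferon call ended without mutant B (adjusted p = 0.386).

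Genes of mesenchymal change and matrix rose. The endothelial to mesenchymal list had 8 of 13 members higher and a median of 0.18 (adjusted p = 0.00249, and 0.347 with an estimated correlation), led by the growth factor Tgfb2 (0.77, SE 0.19), N-cadherin Cdh2 (0.95, SE 0.43), the transcription factor Zeb1 (0.26, SE 0.15) and S100a4 (0.56, SE 0.34). Of the extracellular matrix list, 14 of 18 members were higher, with a median of 0.15 (adjusted p = 0.0119, and 0.380 with an estimated correlation). Its leading members were collagen genes Col6a1 (0.49, SE 0.30), Col3a1 (0.33, SE 0.21) and Col5a1 (0.33, SE 0.24) and fibrillin Fbn1 (0.30, SE 0.19). Markers of alveolar fibroblasts (median 0.39, adjusted p = 0.00646) and adventitial fibroblasts (0.27, 0.0192), each at 0.823 with an estimated correlation, were higher in the same endothelial counts, where 23 marker lists of cell types were tested. For adventitial fibroblasts the median was -0.14 within set A and 0.70 within set B, and for alveolar fibroblasts 0.37 in each. Camera called 6 of them, all higher, these 2 with those of erythroid cells, neutrophils, immune cells and general capillary cells (0.15, 0.0433). The other 17 had an adjusted p of 0.109 to 0.946, and 0 of the 23 were called with an estimated correlation (adjusted p = 0.740 to 0.952). With the set letter as a block, camera no longer called the markers of adventitial fibroblasts (adjusted p = 0.0553), neutrophils (0.0960) and immune cells (0.0589). The matrix call ended without any 1 of the 4 libraries (adjusted p = 0.169 without WT A, 0.0691 without WT B, 0.155 without mutant A and 0.141 without mutant B), and the mesenchymal call ended without WT A (0.312), without mutant B (0.387) and with stricter cells (0.0704).

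Genes of blood cells also rose in the endothelial counts. All 5 haemoglobin genes tested were higher, with a median of 0.88 (adjusted p = 1.77e-23, and 0.347 with an estimated correlation), and all 5 were called when adjusted over the list alone, among them Hba-a1 (0.81, SE 0.17), Hba-a2 (0.88, SE 0.18), Hbb-bt (1.07, SE 0.33) and the haem synthesis gene Alas2 (1.26, SE 0.31). The globin genes are near-identical copies whose reads can be split between them, so their single values are uncertain. Erythroid markers stood higher by the same measure (median 0.90, adjusted p = 4.20e-24, and 0.740 with an estimated correlation), and without mixed cells, a setting chosen after seeing the data that drops cells with at least 1% haemoglobin UMIs, the list was not called and pointed down (adjusted p = 0.575). Neutrophil granule genes (8 of 10 higher, median 0.65, adjusted p = 0.000515) included S100a8 (1.45, SE 0.67), and myeloid inflammation genes (13 of 16, 0.31, 0.00209) included Il1rn (1.00, SE 0.53), Nlrp3 (0.89, SE 0.58), Il1b (0.64, SE 0.43) and Ccl3 (0.62, SE 0.42), and each had an adjusted p of 0.528 with an estimated correlation. Lymphocyte activation genes (8 of 9, median 0.23, adjusted p = 0.00134) included the hyaluronan receptor Cd44 (0.89, SE 0.20), and alternative macrophage activation genes (7 of 8, 0.22, 0.0322) included Retnla (1.74, SE 0.88) and Mrc1 (0.79, SE 0.50), again each at an adjusted p of 0.528 with an estimated correlation.

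These 4 leukocyte lists had medians of opposite sign in the 2 sets. The median log2 ratio of mutant over WT was 1.10, 0.71, 1.10 and 0.74 in set A and -0.41, -0.08, -0.07 and -0.01 in set B, for neutrophil, myeloid, lymphocyte and macrophage genes in that order. Neutrophil markers (median 1.07, 1.81 in set A and -0.86 in set B, adjusted p = 0.0231) and general immune markers (0.38, 1.49 and -0.44, 0.0231) moved with them, each at 0.823 with an estimated correlation. Adjusted over the list alone, 1 gene was called in the neutrophil list (Cxcr4), 1 in the lymphocyte list (Cd44) and 0 in the others. Without mutant A the neutrophil call (adjusted p = 0.450) and the macrophage call (0.680) ended, and without WT A the myeloid (0.378), lymphocyte (0.756) and macrophage (0.355) calls ended. Without mutant B the lymphocyte call ended too (0.103).

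Mitochondrially encoded genes had 11 of 13 members higher and a median of 0.09 (adjusted p = 0.0184, and 0.528 with an estimated correlation), with mt-Nd6 at 0.51 (SE 0.17). That call ended without WT B (0.485), without mutant A (0.141), without mutant B (0.126) and with stricter cells (0.0533). The 16 lists that were not called included those closest to the receptor. VEGFR2 downstream signalling had 9 of 13 members lower (median -0.03, adjusted p = 0.709), VEGF ligands and receptors 7 of 10 higher (0.05, 0.876) and endothelial junctions 11 of 17 lower (-0.03, 0.709). Caveolae and transcytosis genes had 5 of 7 members higher (0.10, 0.172), with Plvap at 0.93 (SE 0.27). Immediate early and dissociation genes had 14 of 16 lower (-0.15, 0.0924) and capillary lipid handling genes 7 of 10 lower (-0.14, 0.0973). The adjusted p was 0.381 for vasoactive signalling (median 0.17), 0.413 for endothelial inflammation and adhesion (0.00), 0.631 for shear responsive KLF genes (-0.04), cell cycle (-0.02) and sex linked genes (-0.03), and 0.709 for contractile smooth muscle (-0.01) and nuclear oxidative phosphorylation genes (-0.03). It was 0.756 for MHC class I presentation (-0.04) and the BMP and TGF-beta pathway (0.01) and 0.993 for surfactant genes (0.00). For cell cycle, sex linked and contractile genes the median lay below 0 while the mean and the test pointed up, and for the BMP list the median lay above 0 while the mean and the test pointed down. For VEGFR2 signalling and surfactant genes the mean lay above 0 while the median and the test pointed down.

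**Figure D2:**
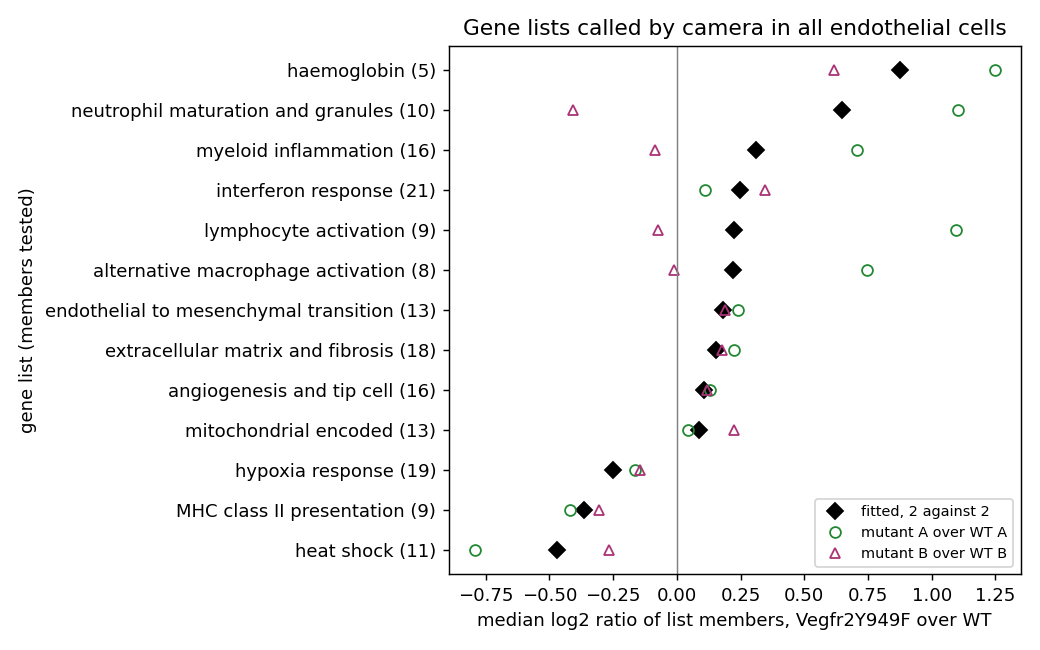
Median log2 ratio, Vegfr2Y949F over WT, of the members of the 13 lists called by camera in all endothelial cells, with the number of members tested in brackets. Black diamonds are medians of the fitted log2 fold changes of 2 against 2 libraries, and green circles and purple triangles are medians of the ratios within set A and set B; heat shock genes lie below 0 in both sets, while the 4 leukocyte lists lie above 0 in set A and below 0 in set B.

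Other lung cells were compared in the same way, in 15 types with at least 20 cells in every library. In alveolar fibroblasts, Gm8797 (ENSMUSG00000103034, chromosome 3, 5750806 to 5751295, plus strand) rose from 39.8 ± 8.37 to 119 ± 24.5 CPM (log2 fold change 1.58, SE 0.22, adjusted p = 0.0213). The potassium channel gene Kcnk1 (ENSMUSG00000033998, chromosome 8, 125995170 to 126030685, plus strand) had 0 UMIs in both WT libraries and 26 and 98 UMIs in the mutants (adjusted p = 0.0193). Of these, 8 of 26 (A) and 82 of 98 (B) lay in cells with at least 3 Gm8797 UMIs, which were 56 of 760 and 106 of 1097 mutant fibroblasts and 8 of 837 and 12 of 697 WT fibroblasts. Over the group Kcnk1 stood at 10.1 CPM in the mutants, 38.9-fold above WT if 3 UMIs are taken as the most that 0 allows there (0.259 CPM). That fold allows for counting error in WT only, and not for error in the mutant level or the spread between libraries. In arterial endothelial cells Hbb-bs (5.74, SE 0.44, adjusted p = 0.000257), Hba-a1 (5.32, SE 0.43, 0.000257) and Hba-a2 (5.25, SE 0.49, 0.000837) rose. In club cells, secretory cells of the airway, the neutrophil genes S100a8 (5.90, SE 0.33, adjusted p = 0.000929) and S100a9 (4.57, SE 0.34, 0.00390) rose.

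These 7 calls, all higher, were the sum over the 15 types by edgeR, and DESeq2 gave 15. Gm8797, a gene model, and Kcnk1, whose average log2 CPM was 2.39, lie outside the rule for named genes and were chosen after their values were seen. In each mutant library 1 arterial cell held 96.5% to 98.9% of the UMIs of each globin gene, and 1 club cell 91.0% to 99.7% of those of S100a8 and S100a9. Without mixed cells the arterial log2 fold changes of Hbb-bs, Hba-a1 and Hba-a2 were 0.04, 0.27 and 0.07, and with stricter cells that of Hbb-bs was -0.67. The adjusted p of Gm8797 in alveolar fibroblasts was 0.0501 without WT A, 0.0689 without mutant A and 0.190 without mutant B, and that of Kcnk1 was 0.0689 and 0.400 without mutant A and B. Without mutant B the arterial globin calls (adjusted p = 0.218, 0.218 and 0.624) and the club S100a9 call (0.0674) ended too. The gene calls in the other cell types were more without any 1 library, 703 (WT A), 138 (WT B), 462 (mutant A) and 333 (mutant B).

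Across cell types, heat shock genes had a median below 0 in all 17 types tested, general capillary cells and aerocytes included, and were called lower in 12. In 10 of the 12 non-endothelial types the median stayed below 0 after subtraction of endothelial RNA, a test chosen after the results were seen, and in alveolar macrophages it went from -0.38 to -0.21, or to -0.10 by the highest marker. With an estimated correlation the adjusted p of each call in this family was 0.914. In aerocytes the median was -0.51 with all 11 members lower (adjusted p = 2.08e-16), and Hsph1 (-0.95, SE 0.20), Hspb1 (-0.95, SE 0.34) and Hspe1 (-0.80, SE 0.22) led. Pericytes had -0.52 (adjusted p = 3.11e-09), with Hspb1 at -1.31 (SE 0.30), alveolar macrophages -0.41 (9.92e-08), with Hspa1a at -1.18 (SE 0.33), and alveolar fibroblasts -0.35 (7.86e-06). Hypoxia response genes had a median below 0 in 16 of 17 types and were called lower in 6, such as aerocytes (-0.26, adjusted p = 0.000158), general capillary cells (-0.23, 0.00294), venous cells (-0.16, 0.00919) and alveolar type 1 cells (-0.10, 0.0138). Interferon response genes were called higher in 6 types. These were general capillary cells (0.28, adjusted p = 5.56e-09), club cells (0.82, 9.62e-08, where neutrophil granule and caveolae genes were higher too), venous cells (0.23, 8.21e-06), aerocytes (0.17, 5.13e-05), alveolar fibroblasts (0.28, 7.47e-05) and smooth muscle cells (0.25, 0.0102). In the alveolar fibroblast counts camera also called immune markers higher (4 of 5 members, median 0.52, adjusted p = 0.00665, and 0.817 with an estimated correlation).

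Antigen presentation and inflammation genes were called in opposite directions in some types, a difference that was not tested, and the adjusted p of each call was again 0.914 with an estimated correlation. MHC class II genes fell in 6 types, among them adventitial fibroblasts (median -0.91, adjusted p = 1.12e-08), T cells (-1.10, 9.92e-08), alveolar fibroblasts (-0.40, 6.20e-05) and alveolar macrophages (-0.47, 0.000882), and rose in myofibroblasts (1.12, 5.14e-05) and club cells (1.13, 0.0131). MHC class I genes rose in 5 types, with all 12 members higher in club cells (0.68, adjusted p = 0.000743) and 10 of 11 in smooth muscle cells (0.41, 0.00159). Markers of other cell types moved in these counts too, in a family of 134 tests chosen after the results were seen, with 35 called and 0 called with an estimated correlation (adjusted p at least 0.717). Endothelial markers were lower in T cells (median -1.08, adjusted p = 0.00260), alveolar macrophages (-1.10, 0.0249), interstitial macrophages (-0.61, 0.0345), alveolar fibroblasts (-0.38, 0.000325) and conventional dendritic 2 cells (-0.52, 0.00397), and higher in myofibroblasts (0.83, 6.67e-05). In club cells all 5 endothelial markers were higher (1.28, adjusted p = 0.0615), as were neutrophil granule genes (3.91, 1.37e-27), caveolae genes (1.14, 0.00400) and alveolar fibroblast markers (0.87, 0.0151), and in adventitial fibroblasts the mesothelial markers were called lower with 2 of 4 members higher (-1.18, 1.04e-08). Myeloid inflammation genes were called lower in 5 types and higher in 2, general capillary cells (0.44, adjusted p = 0.000238, with immune markers higher, 0.50, 0.0164) and aerocytes (0.19, 0.0142). They fell in alveolar macrophages, with 15 of 16 members lower (-0.71, adjusted p = 7.41e-16) and the cytokine genes Il1b at -1.24, Il1a at -1.14 and Ccl3 at -1.26, in interstitial macrophages, with 15 of 16 lower (-0.35, 8.45e-05), and in neutrophils (-0.47, 0.00157). Mesenchymal markers were called higher in the neutrophil counts (4 of 5 members, median 0.81, adjusted p = 0.0151, and 0.817 with an estimated correlation). Cell cycle genes rose in T cells, with all 14 members higher (1.41, adjusted p = 1.07e-05; 0.19 in set A and 1.80 in set B), and in alveolar macrophages (0.37, 0.00392), and fell in conventional dendritic 2 cells (-0.73, 2.51e-06), where interstitial macrophage markers were lower (-1.43, 1.66e-09) and mature dendritic markers higher (0.43, 0.00260), each at 0.817 with an estimated correlation. Contractile smooth muscle genes fell in myofibroblasts (-0.42, adjusted p = 0.00100) and pericytes (-0.28, 0.0101), where smooth muscle markers were lower as well (-0.48, adjusted p = 0.00445, and -0.54, 0.000416, each 0.817 with an estimated correlation).

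Over the 17 types camera made 441 list tests and called 100, with 50 higher and 50 lower, and 147 had an unadjusted p under 0.05. With an estimated correlation 0 were called, and without WT A the count was 189. T cells and club cells rested on few cells in some libraries (76 T cells in WT A and 22 club cells in mutant B), and a list called in 1 type and not in another was not tested for the difference.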

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

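The tests in this part were chosen after the results were seen, except 2 whose outcomes were written down beforehand: on cells of cluster 8 and on the genes used for clustering.

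The change between genotypes differed between general capillary cells and aerocytes for 28 of 12960 genes by the interaction test (564 at an unadjusted p under 0.05), all with the higher value in general capillary cells. Among them, picked after their values were seen, were Cyp4b1 (aerocyte minus general capillary log2 fold change -1.37, adjusted p = 1.33e-11), Aard (log2 fold change 1.34 in general capillary cells against 0.06 in aerocytes, 6.36e-10), Stxbp6 (0.84 against -0.03, 2.49e-06) and the fatty acid carrier Fabp4 (1.09 against -1.53, 0.0396), and aerocyte markers, of which Apln and Fibin are among the 28, were higher in the general capillary sums (5 of 6 members, median 0.47, adjusted p = 1.15e-05, and 0.817 with an estimated correlation). Without cluster 8, 0% of the 28 genes still differed, their median difference went from 0.67 to 0.33, 23 kept their direction and 10 other genes were called. Cluster 8 was set apart because 91.9% of its cells came from the mutants, and its removal changes the general capillary sums alone. A smaller difference was therefore likely in advance, and this setting does not show that cells of cluster 8 carry these calls. Whether the clustering rested on genes that differ between the genotypes could not be decided. General capillary cells were clustered again without the 214 genes at an unadjusted p under 0.05 (1.63% of those tested, 0 called by edgeR). Genes raised in only 1 mutant library can have a larger p and so stay in. After that, a cluster 99.2% mutant and one 98.0% mutant, where 46.2% of all cells were mutant, held 50.8% and 34.6% of the mutant cells of cluster 8 but 1.27% and 1.01% of the other mutant cells. Libraries were not integrated, these clusters came mostly from 1 mutant library each (714 of 779 cells from B, 505 of 547 from A), and 2 more clusters at least 75% mutant (1259 of 1637 and 535 of 700 cells from mutant A) held 20.4% and 8.75% of the other mutant cells and 1.61% and 0% of those of cluster 8, so a cell state that differs between the genotypes and a difference between the pools both stay open, cells of other animals, weighed for Gm8797, among them.

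General capillary cells also differed by the interaction test from venous cells in 4 genes (Plvap 1.29 against 0.16, adjusted p = 0.00101, Samd5 1.99 against 0.58, 0.00623, AW112010 0.59 against -0.53, 0.0293, and Lyve1 0.54 against -0.23, 0.0430). From alveolar fibroblasts they differed in 3 genes (Adgrl3 0.67 against -0.84, adjusted p = 0.00439, Slc16a9 1.04 against -0.01, 0.0148, and Cd44 1.27 against 0.09, 0.0156). From neutrophils, where 19 of 1870 cells of mutant A held 90.9% of its 4703 haemoglobin UMIs against 17 in mutant B and 69 and 357 in WT A and B, they differed in 4 genes (Hbb-bt, adjusted p = 5.77e-06, Snhg15, 0.00125, Chrm3, 0.00682, and Lrrc25, 0.0488), chosen after their values were seen like those before.

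Barcodes below the UMI minimum, which enter no comparison, also held more Gm8797 in the mutants, at 60.3 CPM (92 UMIs) in A and 86.3 CPM (98 UMIs) in B against 20.7 and 25.5 CPM in WT. An even rise in every mutant cell was argued against, since the spread of Gm8797 between cells beyond counting error was 19.9 times as large in the lower mutant library as in the higher WT library (3.90 and 3.13 against 0.0663 and 0.157). A variant of 1 of 2 pooled mice was argued against where cells with Xist come from 1 mouse of a pool, since among cells with at least 10 Xist UMIs and no Y-linked UMI, a minimum that 2.12% and 1.49% of mutant cells with Y-linked UMIs also reached, the intervals of this spread were 3.24 to 6.89 and 1.38 to 2.33 against -0.431 to 0.157 and -0.213 to 0.144 in WT; cells with at least 3 Gm8797 UMIs were unevenly divided, though, 136 with Xist against 282 with Y-linked UMIs in mutant A and 432 against 23 in B, and mutant cells of cluster 8 held more with Y-linked UMIs (300 against 93, and 309 against 216) than other mutant general capillary cells (965 against 1356, and 771 against 1008) or WT cells of cluster 8 (15 against 22, and 19 against 20). Ubb shares 85.7% of the 31-base words of Gm8797, so its counts are uncertain, and in general capillary cells it stood at 374 and 224 CPM in mutant cells of cluster 8, 28.3 and 44.0 CPM in other mutant cells, 37.7 and 33.5 CPM in the 52 and 68 WT cells of cluster 8 and 29.6 and 37.3 CPM in other WT cells. Cells of other animals in the mutant pools may be a source, as a hypothesis: in 100% of 11 type and library units outside general capillary cells, cells rich in Gm8797 had less Rnaset2b, and 10 of 11 had less of the clock genes Nr1d1 and Dbp, while a change of state in some mutant cells, those of cluster 8 among them, stays open. These units come from only 2 mutant libraries, so types of 1 library are not independent.

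Heat shock genes were lower in the mutants in all endothelial cells. Whether WT replicate A alone carried this could not be decided by leaving it out. The list was still called lower (camera adjusted p = 1.05e-07 at the preset correlation). Such a p does not show how well a change repeats between pools, and only WT B was left. With all libraries the adjusted p was 0.347 with an estimated correlation. The median was -0.79 within set A and -0.27 within set B. For 9 of 11 members both mutant libraries lay below both WT libraries. The direction was therefore the same against WT B, with a smaller fall. In general capillary cells of set A the gap lay in cells with Y-linked UMIs (23389 CPM in WT and 14574 in the mutant) more than in cells with Xist (12341 and 11628). In set B these levels were 20339 and 17952, and 19749 and 15543. An effect of the receptor confined to endothelial cells stays open: the median lay below 0 in 100% of 12 non-endothelial types, but in 83.3% once endothelial RNA in them, 0.281% to 18.9% by markers, was subtracted. In pericytes (-0.487 before and -0.485 after), smooth muscle cells (-0.373 and -0.378) and alveolar fibroblasts (-0.313 and -0.297) subtraction hardly moved the median. Endothelial RNA measured in this way does not account for the lower median in these types. In conventional dendritic 2 cells (-0.24 and 0.02) and neutrophils (-0.00017 and 0.34) it ended above 0. Handling of the tissue could contribute, since immediate early and dissociation genes had a median below 0 in 88.2% of 17 types. Camera called them lower in only 3 of these types, though. All types come from the same 4 libraries, so their medians are not independent. General capillary cells with Xist and with Y-linked UMIs were both numerous in each library, so each pool of 2 mice held both sexes. They numbered 1646 and 1265 in mutant A, 1415 and 1080 in mutant B, 1671 and 1771 in WT A and 1418 and 1118 in WT B. Within each set the mutant level was lower in both kinds of cells. Across sets, though, cells with Xist of WT A (12341 CPM) lay below those of mutant B (15543 CPM). The genotype, the mix of the sexes and the part of WT replicate A stay open.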

How the results depend on the processing

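Every setting chosen before the data were examined was run, and 2 more (without mixed cells, without cluster 8) were chosen after seeing the data. The genes changed in all endothelial cells (0 by edgeR) were 9 with DESeq2, 44 with no low-count filter and 1 to 28 with a library left out (9 without WT A, 28 without WT B, 1 without mutant A, 1 without mutant B). The genes changed in general capillary endothelial cells (0) were 14, 64 and 1 to 20 (20, 11, 3 and 1). The genes changed in aerocytes (0) were 3, 29 and 0 to 19 (9, 19, 0 and 7). The gene calls in the other cell types (7) were 15 with DESeq2, 407 with no filter, 4 with stricter cells, 4 without mixed cells and 138 to 703 with a library left out (703, 138, 462 and 333). The gene lists called in all endothelial cells (13) were 0 with an estimated correlation and 8 to 12 with a library left out (9, 12, 11 and 8), and heat shock and angiogenesis were called in 12 of 12 other settings. The gene lists called in the other cell types (100) were 0 with an estimated correlation and 124 to 189 with a library left out (189, 134, 138 and 124). The cell type composition called 0 to 5 types, 5 without WT B and 0 without any other library. The Kdr level (log2 fold change 0.09) was -0.046 without WT B to 0.24 without WT A. With a library left out, the lone library was assumed to vary like the other group, and fewer samples were fitted.

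The T share reversed to 2.35 without WT B (adjusted p = 0.0211) and ranged from -0.92 to 2.35 with a library left out, and Hbb-bs in arterial endothelial cells reversed to -0.67 with stricter cells (adjusted p = 1.00). Of 836 alternatives of 66 single values, 754 were the same, 44 changed sign without a call, 24 were newly called, 12 were no longer called and 2 reversed. Esm1 was newly called without WT A (2.60), WT B (2.47) and mutant A (3.20). Where not given, the cause was not tested.

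The set letter as a block gave 13 genes changed in all endothelial cells, 0 in general capillary cells, 43 genes changed in aerocytes, 260 gene calls in the other cell types, 15 lists in all endothelial cells and 142 in the other types, and a Kdr level of 0.10. Deviations of the libraries of 1 set correlated at 0.722, 0.710 and 0.520 in all endothelial, general capillary and aerocyte cells and at 0.0517 to 0.498 in the other types, and 2 pairs do not show whether the letters pair the libraries.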

Other observations

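The tests in this part, those by DESeq2 apart, were chosen after the results were seen, and the genes named were chosen after their values were seen.

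Alveolar macrophages, which patrol the airspace, had 4 genes lower in the mutants by DESeq2 and 0 by edgeR (131 at an unadjusted p under 0.05). These were the growth factor genes Ereg (log2 fold change -2.72, adjusted p = 2.84e-08) and Areg (-2.25, 0.0181) and the chemokine genes Cxcl3 (-1.24, 0.0409) and Ccl3 (-1.26, 0.0123). In general capillary cells DESeq2 called Samd5 (1.99, adjusted p = 5.04e-08), Plvap (1.29, 0.00122) and Aard (1.34, 0.00827), all higher, of which Plvap also led cluster 8. In venous cells it called the lipid hydroxylase gene Cyp4b1 higher (1.74, adjusted p = 0.00435) and the chemokine gene Ccl21a lower (-2.69, 0.00435). Lymphatic markers were called lower in the same venous counts with 2 of 4 members higher (median -1.22, adjusted p = 1.79e-07, and 0.817 with an estimated correlation), and Ccl21a has near-identical copies, so its value is uncertain. Vasoactive signalling genes rose in general capillary cells by camera (median 0.32, adjusted p = 0.00387, and 0.914 with an estimated correlation). In the same counts markers of aerocytes (0.47, adjusted p = 1.15e-05), neutrophils (1.10, 0.0228), alveolar fibroblasts (0.46, 0.00220), adventitial fibroblasts (0.39, 0.0228) and mesenchymal cells (0.37, 0.0112) were higher, each at 0.817 with an estimated correlation. Surfactant genes rose in alveolar type 1 cells (0.61, adjusted p = 0.000158, and 0.914 with an estimated correlation), where the type's own markers were lower (-0.22, 0.0345) and general capillary markers higher (0.32, 0.000854), each at 0.817 with an estimated correlation.

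Within 20 Mb of Kdr, a stretch chosen after the values of Stbd1 and Scarb2 were seen, 5.44% of tests of 136 genes over 17 types had an unadjusted p under 0.05. Over 408 other stretches, which overlap their neighbours and so are not separate regions, the median was 2.04% and the largest 4.31%. Stbd1 (chromosome 5, 92603041 to 92606579, plus strand) was lower at that level in 5 of 7 types, with a median log2 fold change of -1.84, and Scarb2 (chromosome 5, 92441314 to 92506833, minus strand) in 3 of 17, with -0.31. Other genes of the stretch went both ways at that level: Adgrl3, which led cluster 8, in 5 of 13 types (4 higher, 1 lower), Cxcl2 in 4 of 17 (3 lower, 1 higher), Cxcl1 in 3 of 17, all lower, Limch1 in 3 of 16, all higher, and Igfbp7, Kit and Kdr in 3 each (1 lower, 2 higher). Ereg, Areg and Cxcl3, lower in alveolar macrophages, also lie in this stretch. Neighbouring genes of 1 family, and types of 1 library, are not independent.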
